A study of Mus musculus with 9 samples.

How the data were processed

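RNA sequencing libraries of lung endothelial cells from Tie1-WT (4 libraries) and Tie1-CR mice (5 libraries) were compared. Per the labels' protocols, RNA was extracted with a PicoPure kit and libraries were made with the SMARTer Ultra Low kit, which amplifies cDNA. The submitters' processing notes name STAR 2.7 and the genome builds GRCm38.p6 and mm10. The counting tool, the annotation and the gene filter are not given in the sources used here. How cells were isolated, and the batch, litter, day and time of day of each sample, are not given either. The labels do not say that each library came from a separate mouse, so p-values measure the spread between these samples. Library names run in the order of genotype, so processing order and genotype cannot be told apart.

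The authors deposited a single table, named as TPM, whose values behave as CPM. In each library 100% of the values are whole multiples of a library-specific step, within a tolerance of 0.01 reads, as in counts divided by the total. From the step, 38208696 to 54408116 reads were counted per library, of which 98.3% to 98.6% fall in the table. The design had been written for TPM, and its test on a log scale was kept for CPM. The table holds 9277 genes, each reaching at least 10.0 CPM in some library, so genes below that level cannot be assessed. No value is 0. CPM is not normalized for length, so levels are compared between libraries and not between genes.

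Values were used as log2(CPM + 1), with a filter of at least 1 CPM in at least 4 libraries, which removed no gene. Fold changes on this scale understate changes of low genes. Differences are Tie1-CR minus Tie1-WT. Genes were tested with limma 3.58.1 (trended empirical Bayes, two-sided, R 4.3.3) with Benjamini-Hochberg adjustment and a threshold of 0.05. Adjusted p values of single genes come from this fit unless another test is named. The 47 gene lists, the tests and the rule for named genes were fixed before the data were examined. The 38 lists with at least 5 measured members were tested with camera at a preset inter-gene correlation of 0.01, with an estimated correlation, and with fry. The ribosomal list took symbols by pattern, and so did the histone list, which also took the linker histone gene H1f0. Tie1 and the lists of other cell types were tested by two-sided exact permutation of the libraries, as were list means and the post hoc lists. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.

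The named genes are Tie1, Tek and Angpt2, the 12 largest rises and the 12 largest falls among genes past the threshold whose groups did not overlap, with a mean of at least 2 CPM and without predicted names, and up to 4 members of each list. Members past the threshold were taken by adjusted p. Where a list had none, the 2 with the highest expression and the 2 with the smallest p were taken. Not every gene that this rule selects is reported. Genes named outside this rule are marked as chosen after their values were seen.

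No pair of libraries agreed within counting error alone (lowest chi-square per degree of freedom 21.4), so none repeats the reads of another. This does not exclude separate preparations of the same RNA. Gene positions, GC content and transcript length came from a GENCODE annotation of GRCm38, which matched 9048 of the 9277 symbols (97.5%).

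The fit was tested on simulated data for the 9277 genes. With 100 genes changed by 0.5 log2 and 100 by 1 log2, 86% and 98% were recovered, with 6 false calls (3.16% of calls). Of 20 simulated runs with no change, 4 called at least 1 gene and 0 called a list. Genes were drawn independently in these runs. They therefore cannot show how often lists whose members move together are called by chance. The correction for GC content and length was tested with a planted trend, and 97.9% of genes changed by 1 log2 were recovered.

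Alternatives covered the pseudocount, the filter, TMM scaling and quantile normalization, robust and weighted variance models, an exact Wilcoxon test, a threshold of 0.10, a replicate block, other cell types or the first residual component as a covariate, and each library left out. A correction for GC content and length by natural splines with 4 degrees of freedom, and a fit of annotated genes only, were added after seeing the data. Sex as a covariate was not used because Y-linked genes were expressed in all 9 libraries.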

Results

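RNA was sequenced from endothelial cells isolated from mouse lung. Tie1 is an orphan receptor of the endothelial Tie family that modulates angiopoietin signalling through its partner Tek (Tie2). The labels name wild type mice (Tie1-WT, n = 4 libraries) and mice whose Tie1 resists proteolytic cleavage (Tie1-CR, n = 5 libraries). All 9 library names carry PBS, and no other treatment is analysed here. The values correspond to 38208696 to 54408116 counted reads per library, with no difference in depth between the genotypes past the threshold (exact permutation p = 0.413). A gene at 10 CPM was therefore read 382 to 544 times, a counting error of 4.29% to 5.12% if each read is independent. Copies from the cDNA amplification would make the error larger. Correlations between libraries across genes ran from 0.984 to 0.995 within genotypes and from 0.9776 to 0.9915 between them. The first principal component held 34.4% of the variance and placed the 4 Tie1-WT libraries below 0 and the 5 Tie1-CR libraries above it. The comparison addresses how lung endothelial transcripts differ when Tie1 cannot be cleaved.

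Tie1 transcript was higher in Tie1-CR, at 2433 ± 143 CPM (SD, n = 5) against 2136 ± 42.9 CPM (SD, n = 4), a log2 difference of 0.19. The gene lies on chromosome 4, from 118471191 to 118490061 in GRCm38. Every Tie1-CR library, from 2329 to 2679 CPM, lay above every Tie1-WT library, from 2079 to 2171 CPM (exact permutation p = 0.0079, two-sided, the smallest possible with these group sizes). With quantile normalization the difference was 0.11 log2 (exact permutation p = 0.0238). In the limma fit across all genes, Tie1 did not pass (adjusted p = 0.107). Groups without overlap were found for 10.5% of all genes. Tie1 is also a member of the pan-endothelial list, whose mean log2 difference was 0.11, so its rise is not set apart from that list. Tek, the angiopoietin receptor, measured 1758 ± 83.9 CPM in Tie1-WT and 1935 ± 178 CPM in Tie1-CR (limma adjusted p = 0.318). Angpt2, the ligand that antagonises Tek in a context-dependent way, measured 82.1 ± 9.06 CPM and 69.5 ± 5.29 CPM (limma adjusted p = 0.111). Of the 14 measured members of the Tie receptor pathway list, 0 passed over all genes and 0 when adjusted over the list alone. Its camera adjusted p was 0.255.

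In Tie1-CR, 119 genes were higher and 257 were lower, together 376 genes or 4.05% of those tested (limma, Benjamini-Hochberg adjusted p below 0.05). The falls included transcription factors that growth signals induce rapidly, such as Egr1, Fos and Atf3, and the cytokine signalling inhibitor Socs1. The rises included the neurotrophin receptor Ntrk2, the growth factor binding protein Igfbp5 and the Notch target Hey1. Most differences were small, with a median size of 0.29 log2 among the higher genes and 0.39 among the lower ones. Only 5 genes were higher and 20 lower by at least 1 log2. Of the 376 genes, 340 had groups that did not overlap. Over all genes, 972 (10.5%) did not overlap, where chance gives 1.59%. Lower genes made up 68.4% of the calls, but with TMM scaling there were 186 higher and 188 lower genes (50.3% lower), and with quantile normalization 183 and 190 (50.9% lower). The counts also depended on single libraries. Without Tie1-WT replicate 1 there were 6 higher and 54 lower genes, without Tie1-WT replicate 2 34 and 101, and without Tie1-WT replicate 3 40 and 114. Without Tie1-CR replicate 2 they were 79 and 223, without Tie1-CR replicate 4 52 and 131, and without Tie1-CR replicate 5 74 and 209.

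**Figure D1:**
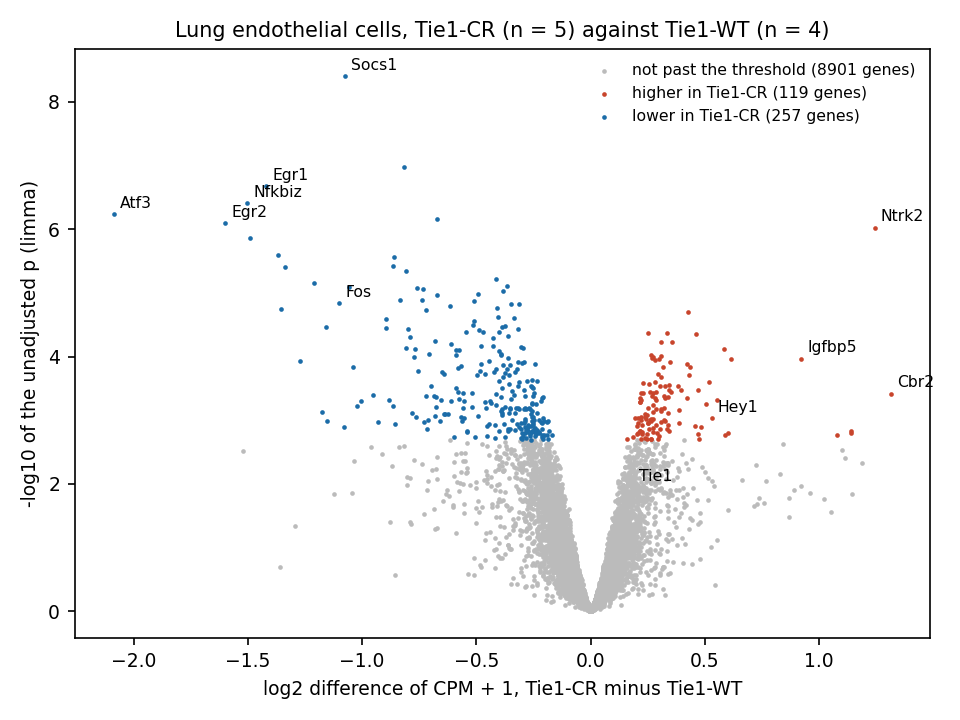
Each point is a gene, placed by its log2 difference of CPM + 1 between Tie1-CR (n = 5) and Tie1-WT (n = 4) and by the -log10 of its unadjusted limma p. Colours mark the 119 higher and 257 lower genes past the threshold; Socs1 has the smallest p, and Tie1 lies among the genes that did not pass.

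Immediate early genes, which cells transcribe quickly after a stimulus, were lower in Tie1-CR. Of 26 measured members, 14 fell and 0 rose over all genes, and 23 fell when adjusted over the list alone, with a mean log2 difference of -0.77 (1.71-fold lower). Egr1, a zinc finger transcription factor on chromosome 18 (34859823 to 34864984), fell from 2214 ± 414 CPM (SD, n = 4) to 821 ± 100.5 CPM (SD, n = 5), or 2.67-fold. Atf3, a stress-induced transcription factor on chromosome 1 (191170296 to 191218039), fell from 184 ± 63.1 to 41.2 ± 7.57 CPM, 4.25-fold. The AP-1 subunit genes Fos and Fosb fell from 1745 ± 287 to 818 ± 176 CPM and from 317 ± 61.1 to 123 ± 26.5 CPM. The limma adjusted p was 0.000657 for Egr1, 0.00105 for Atf3, 0.00485 for Fos and 0.0023 for Fosb. The only member above 0 was Klf10, named after its values were seen, at 0.73 log2 (adjusted p = 0.139), which passed when adjusted over the list alone. The camera test of the list gave an adjusted p of 2.46e-15 (adjusted p = 0.242 with an estimated correlation), and the exact permutation p of its mean was 0.0079. Its mean stayed between -0.88 and -0.70 with each library left out in turn, while the number of members that fell went from 14 to 8 without Tie1-WT replicate 1 and to 9 without Tie1-WT replicate 2.

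Socs1, Nfkbiz, Dusp5, Egr2, Egr3, Ptgs2 and Fam71a were also among the 12 largest falls. Socs1, an inhibitor of cytokine signalling on chromosome 16 (10782240 to 10785536), fell from 58.2 ± 5.55 CPM (SD, n = 4) to 27.1 ± 1.45 CPM (SD, n = 5) and had the smallest adjusted p of all genes (3.6e-05, limma). Nfkbiz, a nuclear regulator of NF-kappaB target genes, fell 2.83-fold (SE 0.15 log2). Dusp5, a nuclear phosphatase of ERK kinases, fell 2.81-fold. Egr2 and Egr3, relatives of Egr1, fell 3.03-fold and 2.56-fold. Ptgs2, the inducible cyclooxygenase, fell 2.08-fold, from 36.4 ± 3.34 to 17.2 ± 3.73 CPM. Fam71a fell 2.53-fold. These 12 genes passed in every alternative fit and with each library left out, though not in the exact Wilcoxon test, where no gene passed. Ptgs2 was the only member of 23 measured genes of endothelial inflammatory activation to pass, over all genes and when adjusted over the list alone (camera adjusted p = 0.498).

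**Figure D2:**
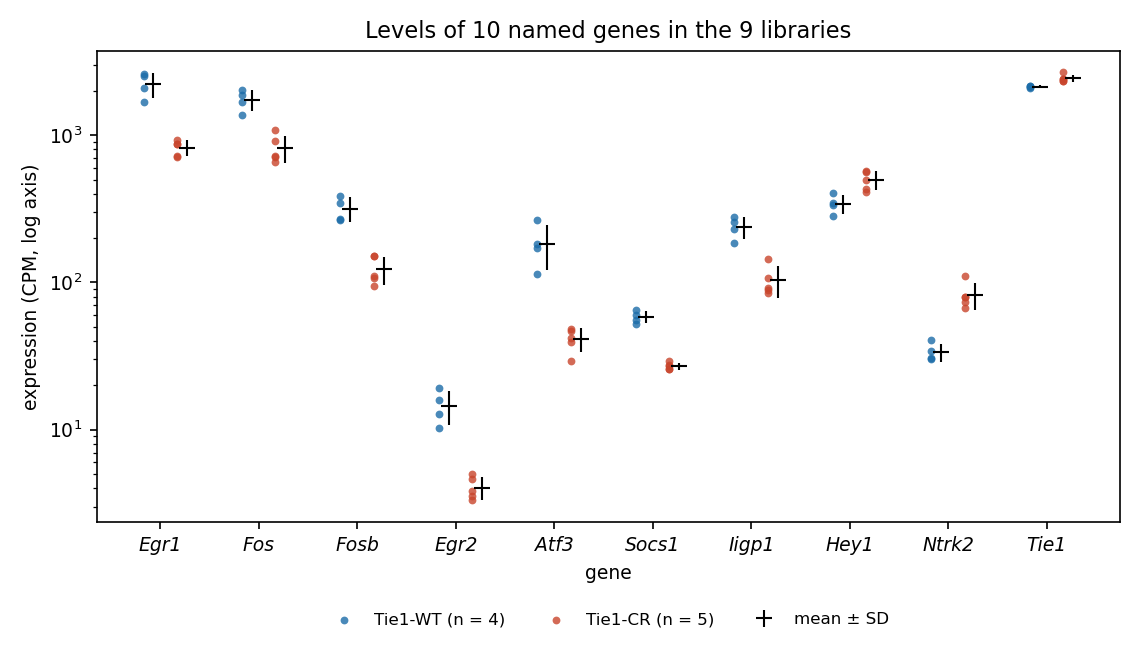
Expression in CPM, on a log axis, of 10 named genes in the 4 Tie1-WT and 5 Tie1-CR libraries, with each point a library and black marks giving the mean and SD. The groups of Egr1, Fos, Fosb, Egr2, Atf3, Socs1 and Iigp1 lie lower in Tie1-CR without overlap, and Tie1 itself differs by a log2 difference of 0.19.

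Interferon response genes lay lower in Tie1-CR as a list. All 34 measured members had a log2 difference below 0, with a mean of -0.40 (1.32-fold lower). Over all genes 5 fell, and 17 fell when adjusted over the list alone. Iigp1, an interferon-induced GTPase on chromosome 18 (60376027 to 60392634), fell from 239 ± 40.2 CPM (SD, n = 4) to 104 ± 24.8 CPM (SD, n = 5) (limma adjusted p = 0.00399). Gbp4, a guanylate-binding protein gene, fell from 328 ± 89.9 to 164 ± 49.8 CPM (limma adjusted p = 0.0254). Irgm1, Gbp3 and Gbp6 fell by 0.68, 0.66 and 1.08 log2, with Gbp6 named after its values were seen. These GTPases belong to multigene families, so reads shared between copies make their levels uncertain. The camera adjusted p of the list was 2.18e-08 (adjusted p = 0.446 with an estimated correlation), and the exact permutation p of its mean was 0.0397. The number that fell was 1 without Tie1-WT replicate 1, Tie1-WT replicate 3 or Tie1-CR replicate 4, 2 without Tie1-CR replicate 5, 3 without Tie1-WT replicate 2, Tie1-WT replicate 4 or Tie1-CR replicate 2, and 9 without Tie1-CR replicate 3. The calls of Gbp4, Irgm1 and Gbp3 ended without Tie1-WT replicate 1 (limma adjusted p = 0.0707, 0.0677 and 0.105). The Gbp4 call also ended without Tie1-WT replicate 3 (0.0653) or Tie1-CR replicate 4 (0.0533), that of Irgm1 without Tie1-WT replicate 2 or 3 or Tie1-CR replicate 4 or 5 (0.0502 to 0.0692), and that of Gbp3 without Tie1-WT replicate 3 or 4 or Tie1-CR replicate 1, 2, 4 or 5 (0.0565 to 0.0778). Those of Gbp4 and Gbp3 ended with robust empirical Bayes (0.056 and 0.054). That of Gbp3 ended with other cell types as a covariate (0.0606), where the difference did not shrink (-0.67 log2 against -0.66). Those of Irgm1 and Gbp3 ended after the GC and length correction (-0.61 and -0.58 log2, 0.0501 and 0.0664). The number was 2 with robust empirical Bayes, 3 with other cell types as a covariate and 2 after the GC and length correction.

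Antigen presentation genes lay lower in the same direction, with none of 20 measured members past the threshold over all genes or when adjusted over the list alone. All 20 had log2 differences below 0, with a mean of -0.42 (camera adjusted p = 0.000654; adjusted p = 0.63 with an estimated correlation; exact permutation p = 0.0873). Without Tie1-CR replicate 2 the mean was -0.25. The class I genes H2-D1 and H2-K1 measured 4964 ± 253 and 2651 ± 247 CPM in Tie1-WT (n = 4) against 4581 ± 524 and 2371 ± 356 CPM in Tie1-CR (n = 5). The peptide transporter Tap1 differed by -0.41 log2 (adjusted p = 0.147, limma) and the class I regulator Nlrc5 by -0.50 (adjusted p = 0.109, limma).

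Notch and arterial genes lay higher in Tie1-CR, with 20 of 21 measured members above 0 and a mean log2 difference of 0.19. Over all genes 2 rose, and 5 when adjusted over the list alone. Hey1, a transcriptional repressor induced by Notch on chromosome 3 (8663359 to 8667256), rose from 342 ± 50.5 CPM (SD, n = 4) to 495 ± 72.9 CPM (SD, n = 5) (limma adjusted p = 0.0353). Jag2, a Notch ligand, rose from 159 ± 12.8 to 196 ± 17.2 CPM (limma adjusted p = 0.0461). The list's camera adjusted p was 3.56e-06 (adjusted p = 0.242 with an estimated correlation), and the exact permutation p of its mean was 0.0079. Both gene calls ended with other cell types as a covariate (adjusted p = 0.0521 for Hey1 and 0.0881 for Jag2), though the differences stayed near those of the fit without it, at 0.55 log2 against 0.53 and at 0.30 against 0.30. They also ended without Tie1-WT replicate 1 (0.105 for both), and that of Jag2 after the GC and length correction (0.20 log2, adjusted p = 0.147). With library weights the Jag2 call ended too (0.0514). That of Hey1 also ended without Tie1-WT replicates 2 or 3 or Tie1-CR replicates 1, 4 or 5, and that of Jag2 without any library but Tie1-CR replicate 5.

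Pan-endothelial markers as a list also lay higher, with a mean log2 difference of 0.11 over 26 measured members, 23 of them above 0. Sox18, an endothelial transcription factor, rose from 828 ± 151 CPM (SD, n = 4) to 1127 ± 92.6 CPM (SD, n = 5), while Erg, another endothelial transcription factor, fell from 50.3 ± 3.61 to 37.5 ± 1.77 CPM (limma adjusted p = 0.0395 and 0.00516). When adjusted over the list alone, 7 members rose and 1 fell. The camera adjusted p was 2.73e-05 (adjusted p = 0.242 with an estimated correlation; exact permutation p = 0.0079). VEGF signalling genes had a mean of 0.07 over 19 members, with 1 rise over all genes, the adhesion molecule Mcam (465 ± 13.8 to 590 ± 57.2 CPM). When adjusted over the list alone, 7 rose and 2 fell (camera adjusted p = 0.00462; adjusted p = 0.309 with an estimated correlation; exact permutation p = 0.198), and without Tie1-WT replicate 3 the mean was 0.04 (0.0379). Among 15 sheddases and inhibitors linked to Tie1 cleavage, 1 rose over all genes and 1 when adjusted over the list alone, the ADAM17 trafficking regulator Rhbdf1 (128 ± 5.45 to 158 ± 7.52 CPM). That list had a mean of 0.07 log2 and a camera adjusted p of 0.00825 (adjusted p = 0.242 with an estimated correlation; exact permutation p = 0.0079), and a mean of 0.05 without Tie1-WT replicate 1. Without Tie1-WT replicate 1 the gene calls of Sox18, Mcam and Rhbdf1 ended (limma adjusted p = 0.117, 0.091 and 0.0511). That of Mcam also ended without Tie1-WT replicate 2 or 3 (0.0653 for both). That of Sox18, at 0.46 log2, ended with other cell types as a covariate (0.44 log2, 0.0778), after the GC and length correction (0.40 log2, 0.0508), and without Tie1-WT replicate 2 or 3 or Tie1-CR replicate 1, 2, 4 or 5 (0.0626 to 0.108).

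Endothelial junction genes and basement membrane genes passed the camera test as lists, with no gene past the threshold and no list mean past exact permutation. The 26 junction genes had a mean of 0.07 log2 (camera adjusted p = 0.00758; adjusted p = 0.309 with an estimated correlation; exact permutation p = 0.0556). The 18 basement membrane genes had a mean of 0.14 log2, with 17 above 0 (camera adjusted p = 0.000416; adjusted p = 0.309 with an estimated correlation; exact permutation p = 0.0952). When adjusted over the list alone, 0 members of either list passed. The vesicle diaphragm gene Plvap measured 5818 ± 700 CPM in Tie1-WT (n = 4) and 6491 ± 251 CPM in Tie1-CR (n = 5), and the collagen gene Col4a1 2361 ± 217 and 2542 ± 151 CPM. Among 19 glycolysis and hypoxia genes, the phosphofructokinase gene Pfkl rose (102 ± 6.85 to 127 ± 6.25 CPM) and Gapdh fell (13.5 ± 0.791 to 9.23 ± 1.65 CPM). Gapdh has many pseudogenes, so its level is uncertain. Over the list alone the calls were 3 higher and 1 lower (camera adjusted p = 0.0199, up; adjusted p = 0.309 with an estimated correlation; exact permutation p = 0.0476). With quantile normalization the calls of the junction, VEGF, sheddase and glycolysis lists ended (adjusted p = 0.174, 0.0609, 0.051 and 0.0512). Their means were then 0.06, 0.07, 0.08 and 0.09 log2, against 0.07 for each in the main fit. The glycolysis list also ended after the GC and length correction (mean 0.07, 0.163) and without Tie1-WT replicate 4 (0.0615), and Pfkl and Gapdh without Tie1-WT replicate 1 (limma adjusted p = 0.066 and 0.106). That of Gapdh also ended with other cell types as a covariate, where the difference stayed near its size (-0.51 log2 against -0.52, 0.0596), and without Tie1-WT replicate 2, 3 or 4 or Tie1-CR replicate 1, 3 or 5 (0.0507 to 0.0818).

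**Figure D3:**
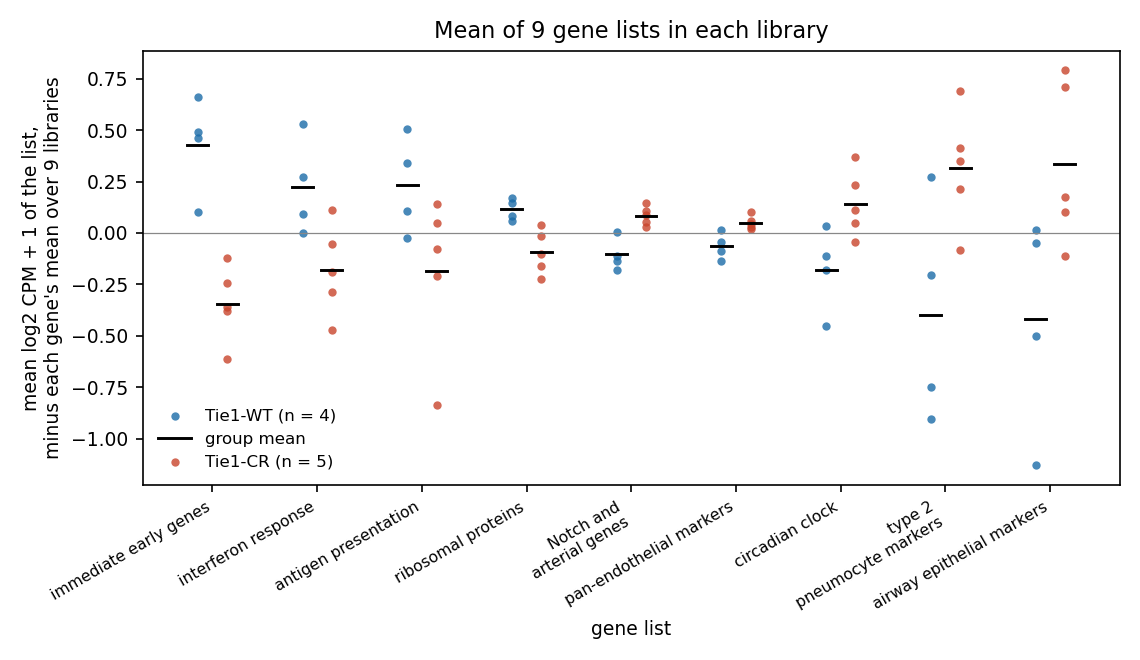
Mean log2 CPM + 1 of 9 gene lists in each library, after each gene's mean over the 9 libraries is subtracted; points are libraries and bars are group means. The immediate early list lies from 0.10 to 0.66 in Tie1-WT and from -0.61 to -0.12 in Tie1-CR, while the interferon list overlaps between the genotypes.

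Genes of lung epithelium were among the largest rises. Cells isolated from lung can carry RNA of other cell types, so these rises may not be endothelial. The source of these transcripts cannot be told from these libraries. Cbr2, a carbonyl reductase of airway cells on chromosome 11 (120729489 to 120732114), rose from 16.0 ± 7.03 CPM (SD, n = 4) to 37.9 ± 4.45 CPM (SD, n = 5). Cyp2f2, a monooxygenase of club cells, rose from 4.95 ± 2.10 to 11.6 ± 3.05 CPM, and Cyp2s1, another monooxygenase, from 8.20 ± 3.48 to 17.7 ± 4.90 CPM. Sftpd, the surfactant protein D gene, rose from 5.88 ± 3.23 to 13.3 ± 3.75 CPM. The limma adjusted p was 0.0232 for Cbr2, 0.0428 for Cyp2f2, 0.0452 for Cyp2s1 and 0.044 for Sftpd. The lists that hold such genes had higher means in Tie1-CR, though libraries of the genotypes overlapped. The 9 type 2 pneumocyte markers had a mean of 0.71 log2, 1 rise over all genes and 7 when adjusted over the list alone. The 6 airway markers had a mean of 0.75, 1 rise and 4 when adjusted over the list alone. Their camera adjusted p values were 9.78e-06 and 0.000416 (adjusted p = 0.309 for both with an estimated correlation). The exact permutation p was 0.0476 and 0.0397, and 0.262 for both after adjustment over the 11 lists of other cell types. The calls of Cyp2f2, Cyp2s1 and Cbr2 ended in some fits, among them robust empirical Bayes (adjusted p = 0.0576, 0.0715 and 0.0532). Without Tie1-WT replicate 3 they were 0.0579, 0.0905 and 0.0571, and that of Sftpd 0.107. Those of Cyp2f2 and Cyp2s1 also ended with other cell types as a covariate (0.99 and 0.91 log2 against 1.14 and 1.08, 0.066 and 0.0607) and after the GC and length correction (1.16 and 1.04 log2, 0.0508 and 0.0676), and that of Sftpd with robust empirical Bayes (0.0636). The Cbr2 call also ended without Tie1-CR replicate 4 (0.0504). The other calls ended without most libraries, the exceptions being Tie1-CR replicate 2 for Cyp2f2, Tie1-WT replicate 2 and Tie1-CR replicate 2 for Cyp2s1, and Tie1-WT replicate 4 for Sftpd.

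Markers of the remaining cell types did not pass as lists. Type 1 pneumocyte markers had a mean of -0.29 log2 over 8 genes (camera adjusted p = 0.236) and platelet markers 0.24 over 6 (camera adjusted p = 0.113). The type 1 list passed with other cell types as a covariate, a component built in part from it (0.00377) and without Tie1-WT replicate 3 (0.0132), with means of -0.46 and -0.47. Its mean was -0.12 without Tie1-WT replicate 2. The platelet list passed without Tie1-WT replicate 1 (mean 0.40, camera adjusted p = 0.00723), while without Tie1-WT replicate 3 its mean turned to -0.06 (0.921). The 8 fibroblast markers had a mean of -0.06 (camera adjusted p = 0.88), which went from -0.33 without Tie1-WT replicate 3 to 0.18 without Tie1-WT replicate 4. Of 3 macrophage markers, Cd68, a lysosomal glycoprotein of macrophages, fell from 10.7 ± 1.30 CPM (SD, n = 4) to 5.30 ± 1.05 CPM (SD, n = 5) (limma adjusted p = 0.00639). The measured macrophage markers went both ways. The neutrophil marker Hdc, the B cell marker Ebf1, 3 mural genes and 2 cardiomyocyte genes had 0 calls over all genes and are too few for a camera test. No T and NK cell, mesothelial or erythroid marker was measured. Y-linked genes exceeded 10 CPM in all 9 libraries, and the sex-linked list had a mean of -0.10 over 4 genes with 0 calls.

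Ntrk2, a neurotrophin receptor on chromosome 13 (58806569 to 59133970), rose from 33.8 ± 4.74 CPM (SD, n = 4) to 81.9 ± 16.7 CPM (SD, n = 5), 1.24 log2 (limma adjusted p = 0.00109). It was the only 1 of the 12 largest rises to pass in every alternative fit and with each library left out, apart from the exact Wilcoxon test. Igfbp5, an insulin-like growth factor binding protein on chromosome 1 (72857932 to 72874884), rose from 19.6 ± 3.03 to 38.5 ± 8.87 CPM (limma adjusted p = 0.0126, and 0.0584 without Tie1-WT replicate 1). The adhesion molecule L1cam rose by 0.61 log2 (SE 0.11) (limma adjusted p = 0.0126, and 0.0585 without Tie1-WT replicate 1). Isyna1, which makes inositol phosphate, rose from 28.3 ± 4.68 to 39.2 ± 1.80 CPM. Clec12b, Zcchc3, H2-K2 and Nhlrc1 rose by 0.60, 0.52, 0.48 and 0.47 log2. The calls of Isyna1, Clec12b, Zcchc3, H2-K2 and Nhlrc1 ended without Tie1-WT replicate 1 (limma adjusted p = 0.0847, 0.105, 0.0769, 0.115 and 0.127). That of Clec12b also ended with other cell types as a covariate (0.55 log2 against 0.60, 0.0831) and that of Nhlrc1 with a pseudocount of 0.1 (0.0505). That of Zcchc3 ended without Tie1-WT replicate 2 or 3 (0.0611 and 0.0513). The calls of Clec12b, H2-K2 and Nhlrc1 ended without most libraries, the exceptions being Tie1-WT replicate 2 for Clec12b and Tie1-CR replicates 1 and 5 for H2-K2. H2-K2 has near-identical relatives in its locus, and its level is uncertain.

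Ribosomal protein genes lay lower in Tie1-CR, with 29 of 32 measured members below 0 and a mean log2 difference of -0.21. Over all genes 4 fell, and 15 when adjusted over the list alone. Rpl10 fell from 17.1 ± 0.703 CPM (SD, n = 4) to 9.79 ± 1.48 CPM (SD, n = 5), Rpl41 from 46.1 ± 1.78 to 30.8 ± 4.73, Rpl3 from 22.7 ± 1.87 to 17.4 ± 0.816 and Rps2 from 19.4 ± 1.12 to 15.0 ± 0.904 CPM. The calls of Rpl41, Rpl3 and Rps2 ended without Tie1-WT replicate 1 (limma adjusted p = 0.0509, 0.0509 and 0.0573), and that of Rps2 without Tie1-WT replicate 3 (0.0508). The camera adjusted p was 1.68e-07 (adjusted p = 0.42 with an estimated correlation; exact permutation p = 0.0159). Ribosomal protein genes have many processed pseudogenes, and these low values are uncertain. The 7 mitochondrially encoded genes had a mean of -0.21 with 0 calls over all genes and 4 lower when adjusted over the list alone (camera adjusted p = 0.00462; adjusted p = 0.446 with an estimated correlation; exact permutation p = 0.0317). The 38 oxidative phosphorylation genes had a mean of -0.08 with 0 calls over all genes and 0 when adjusted over the list alone (camera adjusted p = 0.0218; adjusted p = 0.708 with an estimated correlation; exact permutation p = 0.159). Both calls ended after the GC and length correction, with means of -0.06 and -0.02 (adjusted p = 0.327 and 0.249). That of oxidative phosphorylation also ended with other cell types as a covariate (mean -0.07, 0.0779) and without Tie1-WT replicate 4 (0.19), Tie1-CR replicate 2 (0.0551) or Tie1-CR replicate 3 (mean -0.05, 0.288).

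Some heat shock, apoptosis and cell cycle genes fell in Tie1-CR. Among 18 heat shock genes 4 fell over all genes and 6 when adjusted over the list alone, with a mean of -0.26 log2. The chaperone genes Hspa1a and Dnajb1 fell from 31.9 ± 9.00 CPM (SD, n = 4) to 15.2 ± 4.68 CPM (SD, n = 5) and from 215 ± 33.2 to 143 ± 18.6 CPM, and Dnaja1 and Hsp90aa1 fell by 0.61 and 0.44 log2. Hspa1a has a near-identical copy, so its level is uncertain. The list's camera adjusted p was 0.0218 (adjusted p = 0.639 with an estimated correlation; exact permutation p = 0.0873), and rose to 0.124, 0.0911 and 0.112 without Tie1-WT replicate 2, Tie1-CR replicate 2 and Tie1-CR replicate 4. Of 24 apoptosis genes 3 fell over all genes and 6 when adjusted over the list alone. Among them were the BH3-only gene Pmaip1 (38.3 ± 3.96 to 23.6 ± 1.02 CPM) and Cflar, an inhibitor of death receptor signalling (camera adjusted p = 0.00943; adjusted p = 0.309 with an estimated correlation; exact permutation p = 0.0238). Without Tie1-CR replicate 2 the list's adjusted p was 0.0551. Of 11 cell cycle genes 2 fell over all genes and 5 when adjusted over the list alone. They were the replication genes Pcna (22.0 ± 0.862 to 16.4 ± 0.852 CPM) and Mcm4 (39.8 ± 1.81 to 33.1 ± 1.11 CPM), with a camera adjusted p of 0.00177 (adjusted p = 0.242 with an estimated correlation; exact permutation p = 0.0079). Without Tie1-WT replicate 1, 2 or 3 the calls of the 4 heat shock genes ended (limma adjusted p = 0.0563 to 0.0924). Those of Dnaja1 and Hspa1a also ended with other cell types as a covariate, where the differences stayed near their size (-0.60 log2 against -0.61 and -0.94 against -1.02, 0.0521 and 0.0527). Those of Dnaja1 and Hsp90aa1 ended after the GC and length correction (-0.52 and -0.35 log2, 0.0627 and 0.0831). Tie1-CR replicates 4 and 5 ended those of Hsp90aa1 (0.0537 and 0.051) and Hspa1a (0.0614 and 0.0543) when left out, and Tie1-CR replicate 3 that of Hspa1a (0.056). The Mcm4 call ended without Tie1-WT replicate 1 or 3 (0.0677 and 0.0563). The Cflar call, at -0.35 log2, ended with TMM scaling (-0.33 log2, 0.0614), after the GC and length correction (-0.28 log2, 0.096) and without any library but Tie1-WT replicate 4 and Tie1-CR replicate 5 (0.0546 to 0.129).

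In the unfolded protein response list, 3 of 26 genes fell over all genes, and 6 fell and 1 rose when adjusted over the list alone (camera adjusted p = 0.316). They were Atf3, the translation-controlled transcription factor gene Atf4 (270 ± 25.8 CPM, n = 4, to 185 ± 29.8 CPM, n = 5) and the eIF2 phosphatase subunit gene Ppp1r15a (824 ± 161 to 478 ± 55.0 CPM). The list of YAP and TAZ genes had 2 falls among 12 over all genes, the target gene Cyr61 and Wwtr1, which encodes TAZ itself, and 2 higher and 3 lower when adjusted over the list alone (camera adjusted p = 0.389). TGF-beta and BMP genes had 1 rise, the inhibitory Smad gene Smad7, and 1 fall, the repressor gene Zeb1, among 27, with 3 higher and 2 lower when adjusted over the list alone (camera adjusted p = 0.418). FOXO1 targets had 1 rise (Igfbp5) and 1 fall (Tob1) among 18, with 1 higher and 5 lower when adjusted over the list alone (camera adjusted p = 0.502). Among 11 glucocorticoid targets 1 fell, the EGFR inhibitor gene Errfi1, with 1 higher and 3 lower when adjusted over the list alone (camera adjusted p = 0.512). In the shear stress list of 20 genes, the nitric oxide synthase gene Nos3 rose from 127 ± 5.15 to 155 ± 9.28 CPM, with 3 higher when adjusted over the list alone (camera adjusted p = 0.0838, and 0.0391 without Tie1-WT replicate 3 and 0.0218 without Tie1-CR replicate 2, 0.038 with library weights and 0.049 with a minimum of 5 CPM in 4 libraries). Without Tie1-WT replicate 1 the calls of Atf4, Ppp1r15a, Cyr61, Wwtr1, Smad7, Zeb1, Errfi1 and Nos3 ended (limma adjusted p = 0.0847, 0.0502, 0.0911, 0.0509, 0.0675, 0.127, 0.0573 and 0.0801). The Zeb1 call, at -0.29 log2, also ended with TMM scaling (-0.26 log2, 0.0537) and without Tie1-WT replicate 2 or 4 or Tie1-CR replicate 3, 4 or 5 (0.0627 to 0.097), and the Smad7 call, at 0.34 log2, after the GC and length correction (0.29 log2, 0.0689). Tie1-WT replicate 2 ended the calls of Atf4, Cyr61, Smad7 and Nos3 when left out (0.0757, 0.0771, 0.056 and 0.055), Tie1-WT replicate 3 those of Atf4, Cyr61 and Smad7 (0.0579, 0.0585 and 0.0565), and Tie1-CR replicate 4 that of Cyr61 (0.0544).

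Vessel type lists other than the arterial list did not pass. The venous receptor gene Ephb4 rose from 792 ± 37.0 CPM (SD, n = 4) to 1000 ± 32.1 CPM (SD, n = 5), but the venous list of 16 genes did not pass, with 1 higher when adjusted over the list alone (camera adjusted p = 0.204). Aerocyte, general capillary and lymphatic lists of 15, 14 and 7 genes had 0 calls over all genes and 0 when adjusted over the list alone (camera adjusted p = 0.512, 0.236 and 0.52). Coagulation genes (11) had 0 calls over all genes and 1 lower over the list alone (camera adjusted p = 0.88). Cholesterol (19), fatty acid (16) and histone (10) genes had 0 calls over all genes, and 0, 0 and 1 higher when adjusted over the list alone (camera adjusted p = 0.681, 0.397 and 0.367). Without Tie1-CR replicate 5 the histone list passed (adjusted p = 0.0332). The mean, median and camera direction differed in sign for the shear stress, coagulation, venous, aerocyte, lymphatic, TGF-beta and fibroblast lists, so these have no clear direction.

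Clock genes had a mean log2 difference of 0.32 over 13 measured members, 10 of them above 0. None passed over all genes, and 3 were higher and 1 lower when adjusted over the list alone. Per2, Tef and Nr1d1 measured 30.7 ± 8.81, 118 ± 30.3 and 248 ± 80.7 CPM in Tie1-WT (SD, n = 4) against 55.6 ± 15.4, 187 ± 48.5 and 372 ± 98.5 CPM in Tie1-CR (SD, n = 5). Their limma adjusted p values were 0.0545, 0.0948 and 0.158. The camera adjusted p of the list was 0.00462 (adjusted p = 0.309 with an estimated correlation), and the exact permutation p of its mean was 0.0317.

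Over the 38 lists with at least 5 measured members, 19 passed the camera test with a preset correlation of 0.01, 10 higher and 9 lower. With an estimated correlation 0 passed, and 5 had an unadjusted p below 0.05. In fry, which asks whether a list moves on balance in 1 direction, 7 passed. Exact permutation of list means gave 14 lists below 0.05 before adjustment and 0 after it (smallest adjusted p = 0.0603). Of 100 splits of the 9 libraries, the real 1 included, 9 gave at least 19 lists.

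The differences followed the GC content of the genes. Across 9048 annotated genes, which are not independent replicates, the log2 difference had a Spearman correlation of 0.42 with GC content. The median GC content was 56.9% for the higher genes, 46.6% for the lower genes and 49.8% for all genes. Across genes within a library, the correlation of expression relative to the 9-library mean with GC content averaged -0.19 ± 0.117 in Tie1-WT (SD, n = 4) and 0.14 ± 0.135 in Tie1-CR (SD, n = 5) (exact permutation p = 0.0159). After each library's trend with GC content and transcript length was removed, a step chosen after seeing the data, 111 genes were higher and 174 lower, and 218 of the 376 calls remained.

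**Figure D4:**
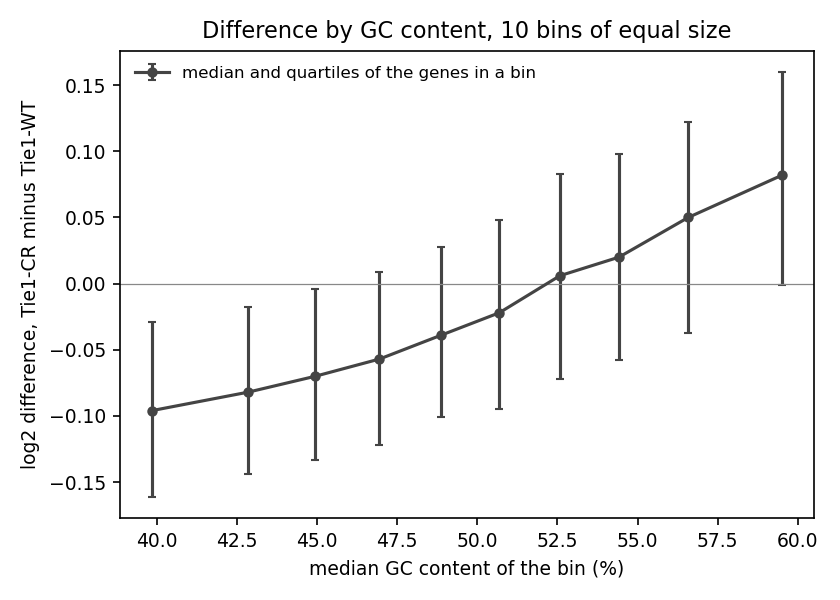
Median log2 difference between Tie1-CR and Tie1-WT, with quartiles as bars, in 10 bins of about 905 genes ordered by GC content in percent. The median goes from -0.10 in the bin with the lowest GC content to 0.08 in the bin with the highest.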

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

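The tests of handling, of GC content and length and of the calls that this correction ended, of single libraries, and of positions on chromosomes 17 and 4 were chosen only after the results were seen; the test of other cell types was written before. A library was listed here when its gap to its nearest neighbour in the same genotype took up most of the group's range (Dixon's 95% criterion). Of 340 groups of values tested, 11 met it, fewer than the 5% that chance gives.

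In Tie1-CR replicate 4, Tie1 measured 2679 CPM against 2329 to 2423 in the other 4 libraries, and Ntrk2 110 CPM against 66.7 to 79.2. In Tie1-WT replicate 4, Irgm1 measured 219 CPM against 147 to 155 in the other 3 libraries, Gja1 31.6 against 21.6 to 23.2, and mt-Cytb 796 against 662 to 683. The general capillary list had a mean of -0.12 log2 there, against values near 0 in the other 3. In Tie1-WT replicate 3, Cav1 measured 2628 CPM against 2916 to 2940, and in Tie1-WT replicate 1 Slc27a4 measured 24.1 CPM against 29.6 to 30.2. In Tie1-CR replicate 5, Akap5 measured 8.84 CPM against 3.77 to 5.21, and in Tie1-CR replicate 2 Lmo7 180 CPM against 146 to 155. The glycolysis list had a mean of 0.10 log2 in Tie1-CR replicate 1, against -0.01 to 0.02 in the other 4.

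The fall of immediate early genes is a pattern that cell isolation could produce. It argues against a trend with GC content and length that the list mean was still -0.77 after that correction. With the component of other cell types as a covariate the list mean was -0.79. That covariate left the rise of the club cell gene Cyp2f2 at 0.99 log2 against 1.14. It therefore cannot decide whether RNA of other cell types contributes. Different handling of the genotypes stays open. Heat shock genes, which handling also induces, had a mean of -0.26 log2 (exact permutation p = 0.0873), and with no day or time in the labels handling and genotype cannot be told apart. An effect of the Tie1 allele is untested as the cause.

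The lower interferon list may reflect a state of single mice or an effect of the allele. With each library left out in turn, the mean nearest 0 was -0.30 (without Tie1-WT replicate 4), which argues against a single library as the whole cause. After the GC and length correction it was -0.34. All 34 members lie off chromosome 17, so their mean of -0.40 is the list mean itself and no separate test. An MHC variant that acts only on genes of its own region could not lower these members. An indirect effect of such a variant stays open. An infection or exposure shared by the Tie1-WT mice was not tested, and stays open beside the genotype.

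The excess of calls may in part follow GC content. Of the 376 calls, 218 remained after the GC and length correction, which argues against the trend as the whole cause. For the 150 annotated calls that ended, the median size of the log2 difference went from 0.28 to 0.21 with a median standard error of 0.06 before and after. These genes were chosen because their calls ended, so their smaller differences do not test the trend. Position argues against variants carried along with the Tie1 allele, acting on genes near it, as the source of most calls. Within 15 Mb of Tie1, 4.32% of 185 genes were called (8 genes) against 4.06% of the others (Fisher's exact test p = 0.85). A share over the whole window cannot exclude such variants acting on a few of these genes. A carried variant that acts on genes elsewhere stays open. Whether the GC trend arose in the cells or in library preparation was not tested.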

How the results depend on the processing

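The GC and length correction and the fit of annotated genes only were chosen after the data were seen; the other alternatives were planned. Higher and lower genes, 119 and 257, became 186 and 188 with TMM scaling, 183 and 190 with quantile normalization, 245 and 416 with library weights, 314 and 592 at an adjusted p below 0.10, 326 and 580 with the first residual component as a covariate, 64 and 145 with other cell types as a covariate, 74 and 209 in 8 libraries with no replicate block, and 37 and 145 with the replicate block. The first residual component was taken from the spread within genotypes, so it leaves the differences unchanged and removes spread by construction. For the other changes the cause was not tested beyond the looser threshold and the smaller number of libraries. The exact Wilcoxon test called 0 and 0 genes (smallest adjusted p = 0.151, with 1498 genes below 0.05 unadjusted), since 9 libraries allow no p below 0.0159, and so says nothing about stability. With each library left out in turn, 6 to 110 genes were higher and 54 to 245 lower, the lowest without Tie1-WT replicate 1, and 17 to 21 lists passed. None of the 376 calls changed sign in any fit. With an estimated correlation 0 lists passed instead of 19, and with fry 7. Replicate numbers do not pair the samples: deviations of same-numbered libraries correlated at -0.14, 0.00, -0.06 and 0.19, and 1 of 4 matched best with its own number. Tie1 differed by 0.20 log2 with the replicate block (exact p = 0.125, the smallest 4 pairs allow), by 0.11 with quantile normalization and by 0.15 to 0.20 with each library left out. The fibroblast list, with a mean of -0.06 but a camera direction of up, had a mean of -0.40 and passed as lower (adjusted p = 0.000643) with other cell types as a covariate, a component built in part from that list. The type 1 pneumocyte list passed with the replicate block (-0.43, adjusted p = 0.025). A change of direction, for lists that of camera, is counted only where either fit passes. Apart from the Wilcoxon test, 25 of 59 called named genes lost their call in some fit and 39 with some library left out, while 20 kept it with each library left out. Named genes gained a call in 30 combinations of gene and fit, and in 7 of gene and left-out library. Angpt2, Per2, Tef and Nr1d1 did so with the first residual component as a covariate (limma adjusted p = 0.0486, 0.0412, 0.0433 and 0.0415). Lists kept direction and side of the threshold in 554 of 570 alternative fits and in 329 of 342 with a library left out. All of these fits used camera with the preset correlation of 0.01. The counts therefore cannot show that list calls are stable, since 0 lists passed with an estimated correlation. The content of other cell types stayed at 0 lists in every fit where it could be computed. With 11 lists and a smallest exact permutation p of 0.0079, a list cannot pass on its own after adjustment. Fits with fewer libraries or with pairs allow even less, so this says little about stability. The filter of no minimum removed nothing and tests nothing, the sex covariate was not run, and the Wilcoxon test has no list form.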

Other observations

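The tests of the terminal oligopyrimidine genes and of the clock phases were chosen only after the list results were seen; the splits of the libraries were written before.

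Genes whose transcripts start with a terminal oligopyrimidine tract, which couples translation to growth signals, lay lower in Tie1-CR beyond the ribosomal proteins. Of 23 measured translation factors and related host genes, 22 had log2 differences below 0, with a mean of -0.20 (exact permutation p = 0.0159). Reads shared with pseudogenes, a limit of the ribosomal protein values, were not assessed for these genes. Pabpc1, the poly(A) binding protein gene, fell by 0.41 log2, and the snoRNA host genes Gas5, Snhg1 and Snhg8 fell by 0.61, 0.81 and 0.54. These 4 genes were named after their values were seen.

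A hypothesis is that ribosomal protein genes and other genes of this class may be lower together. Because the 4 called genes could carry the mean, it was computed again without them, after the mean of all 23 genes had been seen. The other 19 genes had a mean of -0.12 log2, with 18 below 0 (exact permutation p = 0.0476). This follows in large part from the values already seen and adds no support, so the hypothesis stays untested. After the GC and length correction the mean of all 23 genes was -0.14 and that of the ribosomal list -0.16.

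A second hypothesis is that the genotypes may have been sampled at different clock phases. The 8 genes of the Per and Rev-erb phase (Per, Rev-erb and PAR bZIP genes and Ciart) had a mean of 0.52 log2, and Arntl and Clock, which peak at the opposite phase, a mean of -0.42. The difference between the groups of genes gave an exact permutation p of 0.0397. Several genes of the first group had been seen before the test, and Arntl and Clock alone gave an exact permutation p of 0.0635, so the phase stays open. A direct effect of the genotype on the clock stays open and untested.

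Epithelial transcripts varied between libraries of the same genotype. Sftpc, the surfactant protein C gene, measured 190 ± 125 CPM in Tie1-WT (SD, n = 4) and 307 ± 91.2 CPM in Tie1-CR (SD, n = 5), and Lyz2, expressed by myeloid cells and type 2 pneumocytes, 37.8 ± 21.8 and 76.2 ± 21.9 CPM (limma adjusted p = 0.181 and 0.0669). Both were named after their values were seen.

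The number of called genes was set against other splits of the 9 libraries. Of 100 splits, the real one included, 1 gave as many as 119 higher genes, where the highest other split gave 25, and 1 gave as many as 257 lower genes, where the highest other gave 2. No other split among these reached either count, which makes chance an unlikely source of both. Not every possible split was drawn, so chance is not fully excluded. For the 19 gene lists, 9 of 100 splits gave as many, and the highest other split gave 22. Chance cannot be excluded for the number of lists.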
